A study of Homo sapiens with 8 samples.

How the data were processed

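RNA was measured on 8 oligonucleotide expression arrays of the 3' in vitro transcription type, 1 for each combination of 2 human lung cancer cell lines (A549, without an activating EGFR mutation, and HCC827, with one), 2 cultures and 2 treatments. Per the labels, 2D cultures were grown for 7 days from 200000 cells in dishes of 21 square centimetres, and 3D cultures for 14 days from 100000 cells on a collagen scaffold. The 3D samples were lysed with beads for 5 min at 50 Hz and extracted with a micro column kit, whereas the 2D samples went through a mini column kit, so culture and RNA preparation differ together. From every sample 100 ng of total RNA was amplified and biotin-labelled. Treated cultures received 1 µM gefitinib and controls received no inhibitor. In 3D it was added after 11 days for 3 days; a start after 4 days is given in a sentence that also says 3D and was read as the 2D start, and the duration in 2D is not stated. There were no replicates of any condition.

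The deposited values are log2 signals of 49495 probe sets after robust multi-array averaging (RMA) in R 3.2.1, per the submitters' processing notes. Array medians were 7.34 (A549 3D control), 7.30 (A549 3D gefitinib), 7.32 (HCC827 3D control), 7.27 (HCC827 3D gefitinib), 7.32 (A549 2D control), 7.32 (A549 2D gefitinib), 7.33 (HCC827 2D control) and 7.31 (HCC827 2D gefitinib). The spread and range of the values were those of RMA output on the log2 scale, with no further centring. The number of arrays limits precision. A genome build is not given in the sources used here. Of the probe sets, 102 were control probe sets. The array annotation listed 46617 probe sets; 45278 carried 1 gene symbol and were used, 1333 carried several and were left out, and 2782 were not listed. Of the 45278, 45208 matched a gene of the RefSeq table (assembly GRCh38.p14), used for symbols only, and 70 did not. For each of 18244 genes the probe set with the highest mean was used. Genes above the array median in at least 2 arrays were tested, which left 11926 and set aside 6318.

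A linear model with 6 coefficients (a mean, the line, the culture, the treatment, and the interactions of line with culture and line with treatment) was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a variance trend. It leaves 2 residual degrees of freedom, plus 2.36 from the prior. Without replicates, the residual is the change of the gefitinib effect between 2D and 3D within a line, so an effect is tested against that change and not against replicate scatter, and the change itself is not tested. Standard errors (±) are those of this fit. 8 contrasts were tested with Benjamini-Hochberg adjustment over the tested genes in each, and an adjusted p under 0.05 was the threshold. All tests were two-sided. Differences are given as log2 values. For gefitinib within each line and culture, the difference between 1 array and 1 array is given without a replicate error; for HCC827 3D, a fit without the HCC827 2D arrays also gives errors, with the spread taken from A549.

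Before the data were examined, 27 gene lists, the comparisons, the filter, the alternatives and the rule for named genes were fixed. By that rule the text takes from the 10 largest rises and 10 largest falls past the threshold with the same sign in every pair of arrays, the up to 4 largest members past the threshold of a list discussed (2 where none passes), and EGFR, DUSP6, ETV5, SPRY4, CCND1, MKI67, CDH1 and VIM. For untested responses it takes from the 10 largest each way, and the 8 largest each way for 3D against 2D. For the 2 contrasts between lines, only EGFR and DUSP6 were given single values, a restriction made after the values were seen. Lists with at least 5 measured members were tested with camera at a preset correlation between genes of 0.01, which left out 1 list with 4 members. Camera was repeated with an estimated correlation, and the rotation test fry was run. That estimate rests on the 2 residual degrees of freedom, so few lists could pass with it, and a list that misses is not shown to be unchanged. The preset value in turn takes the genes as nearly independent. Each list median of an untested response was set against 10000 random lists of equal size.

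The fit was tested on simulated data with 11926 genes. For the mean culture effect, 92 of 100 genes changed by log2 1 and 98 of 100 changed by log2 2 were called, with 9 of 11726 unchanged genes. For gefitinib in HCC827 the counts were 61 of 100, 92 of 100 and 13 of 11726. A list shifted by log2 1 was called in 20 of 20 runs in each contrast, and 7 of 500 (culture) and 6 of 500 (gefitinib) unshifted lists were called. The simulated noise was independent between genes, so these runs do not measure false list calls among correlated genes. It also had the same size in both lines. The real gefitinib differences spread more in HCC827 (SD 0.43 in 2D, 0.42 in 3D) than in A549 (0.16, 0.17). The simulated rates therefore do not describe a fit with unequal lines.

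The alternatives were the mean of a gene's probe sets, the probe set with the largest variance, no filter, a filter at the 75th percentile, cyclic loess, centring on array medians, a variance prior without trend or with robust estimation, an additive model, all pairwise interactions, each line fitted alone, a 2-fold minimum and leaving out each array. Leaving out both HCC827 2D or both HCC827 3D arrays was added after the data were seen. Control probe sets served for measures of RNA integrity, which were compared with an exact permutation test over all 70 splits of 4 against 4 arrays. Correlations of responses across genes were judged against a bootstrap over genes.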

Results

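Expression of 18244 genes was measured on 8 arrays of the lung cancer cell lines A549 and HCC827, grown in 2D or on a 3D collagen scaffold, with or without 1 µM gefitinib, an inhibitor of the EGFR kinase. HCC827 carries an activating EGFR mutation and A549 does not. The design asks how the lines differ, what the scaffold changes, and how each line responds to gefitinib in each culture. Each condition had 1 array. The closest arrays were the A549 2D pair (r = 0.996 across probe sets) and the A549 3D pair (0.995), ahead of the HCC827 3D pair (0.978) and the HCC827 2D pair (0.977). Probe sets are not independent replicates. In HCC827 genes downstream of EGFR signalling differed in opposite directions in the 2D pair and the 3D pair. The 2D arrays of that line are therefore referred to below by their labels. Every gefitinib value of that line in 2D, or averaged over cultures, depends on them. The residual of the fit holds this opposition too, so the standard errors, p-values and gene counts of all 8 contrasts also depend on these arrays. A gene that misses the threshold in the line, culture or A549 contrasts may do so because of it.

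The first comparison asked how the lines differ, over 4 arrays of each. HCC827 stood above A549 in CDKN2A, a cell cycle inhibitor locus, by log2 6.19 ± 0.10, in LCP1, an actin-bundling protein, by 5.64 ± 0.11 and in ADGRF1, an adhesion receptor, by 5.61 ± 0.21. It was also higher in the surfactant-associated SFTA2 by 5.44 ± 0.11, in the matricellular protein CCN1 by 5.30 ± 0.28 and in the lung lineage factor NKX2-1 by 5.21 ± 0.13. A549 stood above HCC827 in aldehyde dehydrogenases and aldo-keto reductases: the difference was -7.36 ± 0.13 for ALDH1A1, -7.28 ± 0.09 for ALDH3A1, -7.17 ± 0.16 for AKR1C2, -7.05 ± 0.33 for AKR1B10 and -6.42 ± 0.22 for AKR1C1. Carbonic anhydrase CA12 (-7.12 ± 0.16), the fibrinogen chains FGA (-6.35 ± 0.15) and FGB (-6.27 ± 0.15) and the neuropeptide NTS (-6.32 ± 0.09) were also lower in HCC827. Among markers named in advance, EGFR was higher in HCC827 by 2.62 ± 0.21 (adjusted p = 0.00178), the epithelial cadherin CDH1 was higher by 1.29 ± 0.08 (0.00106) and the mesenchymal filament VIM was lower, at -2.71 ± 0.29 (0.00318). Each of these genes differed in the same direction in 4 of 4 pairs of arrays, which the naming rule required of those outside the markers. The largest adjusted p of those outside the markers was 7.08e-04.

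Gene groups separated the lines in the same way. Of 21 NRF2 targets, which serve oxidative defence, 0 were higher and 20 lower in HCC827 over all genes (0 and 20 adjusted over the list alone), with a median of -2.14. Camera gave the list an adjusted p of 4.04e-10, and adjusted p = 0.577 with an estimated correlation. Epithelial genes were mostly higher in HCC827: 19 higher and 2 lower of 23 (19 and 2 adjusted over the list alone), median 2.20, camera adjusted p = 7.03e-09, and adjusted p = 0.577 with an estimated correlation. They included the splicing regulator ESRP1 (4.68 ± 0.19), the tight junction proteins CLDN4 (4.57 ± 0.15) and CLDN7 (4.50 ± 0.10) and the cadherin CDH3 (4.73 ± 0.20). Interferon-response genes were 22 higher and 2 lower of 25 (22 and 2 adjusted over the list alone), median 1.68, led by IFI27 (4.84 ± 0.12), IFI44 (3.91 ± 0.08), BST2 (3.66 ± 0.16) and ISG15 (3.32 ± 0.16). For them camera adjusted p = 1.48e-08, and adjusted p = 0.763 with an estimated correlation. DUSP6 (-0.40 ± 1.18, adjusted p = 0.802), a phosphatase induced by ERK signalling, and CCND1 (-0.82 ± 0.73, 0.408), a cyclin, did not pass the threshold. By limma, 5736 of 11926 genes passed, 2625 higher and 3111 lower in HCC827, and 880 and 1009 of these differed by 2-fold or more. Leaving out the A549 3D control, 3D gefitinib, 2D control or 2D gefitinib array gave 1772, 1730, 1831 and 1801 genes.

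The second comparison asked what differs between 3D and 2D culture, as the mean over both lines (4 arrays against 4). In 3D, the lipoprotein lipase inhibitor ANGPTL4 was higher by log2 3.74 ± 0.66 (adjusted p = 0.0144) and the nuclear noncoding RNA MALAT1 by 3.11 ± 0.09 (0.00418). Also higher were the gel-forming mucin MUC5B by 2.93 ± 0.32 (0.00565), FER1L4 by 2.88 ± 0.13 (0.00418) and the splicing protein SRRM2 by 2.77 ± 0.13 (0.00418). Lower in 3D were SRP9, a signal recognition particle subunit (-2.47 ± 0.10, adjusted p = 0.00418), the mitotic cyclin CCNB1 (-2.26 ± 0.54, 0.0301) and SDHD of mitochondrial complex II (-2.20 ± 0.12, 0.00418). So were the mitochondrial ribosomal protein MRPL19 (-2.13 ± 0.14, 0.00418) and the calponin CNN3 (-2.09 ± 0.11, 0.00418). Each moved the same way in 4 of 4 pairs of arrays, as the naming rule required. VIM was lower (-1.04 ± 0.29, adjusted p = 0.0418), below 0 in the 2 HCC827 pairs of the 4; it did not pass with the mean of its probe sets (-0.87, adjusted p = 0.0930), with cyclic loess (-0.96, 0.0708) or in an additive fit (-1.04, 0.206). By contrast, EGFR (0.48 ± 0.21, 0.130), DUSP6 (0.98 ± 1.18, 0.527) and CDH1 (0.06 ± 0.08, 0.548) did not pass. CDH1 passed as lower in 3D with the mean of its probe sets (-0.40, adjusted p = 0.0172) and with its largest-variance probe set (-0.86, 0.00250), so its call depends on the probe set.

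Airway secretory genes were higher in 3D, 14 higher and 0 lower of 19 (14 and 1 adjusted over the list alone), with a median of 1.02. Beside MUC5B these included MUC16 (2.44 ± 0.09), the copper carrier CP (2.20 ± 0.27) and the immunoglobulin transporter PIGR (2.00 ± 0.08). Camera gave the list an adjusted p of 0.00142, and adjusted p = 0.928 with an estimated correlation. Interferon-response genes were lower, 2 higher and 15 lower of 25 (2 and 15 adjusted over the list alone), median -0.51, with IFIT1 at -1.85 ± 0.21, OAS1 at -1.59 ± 0.26 and the RNA sensor IFIH1 at -1.22 ± 0.16. This list had camera adjusted p = 2.66e-04, and adjusted p = 0.928 with an estimated correlation. Cell cycle genes had a median of -0.67, 34 of 39 below 0, with 0 higher and 2 lower over all genes (0 and 0 adjusted over the list alone), namely CCNB1 and the replication helicase subunit MCM6 (-1.67 ± 0.42, adjusted p = 0.0337). The cell cycle list had camera adjusted p = 0.00333, and adjusted p = 0.928 with an estimated correlation. Its HCC827 pairs were unlike, as labelled. The 3D minus 2D difference of the gefitinib pair minus that of the control pair had a median of -3.22 (39 of 39 below 0), against -0.25 in A549. For culture in HCC827, MKI67 stood at 1.84 without the 3D gefitinib array and at -1.65 without the 3D control array. The mean fall is thus not shown for untreated HCC827. Hypoxia genes had a median of 0.90, 9 higher and 0 lower of 24 (5 and 0 adjusted over the list alone), among them NDRG1 (2.59 ± 0.70, adjusted p = 0.0403), but the list did not pass camera (adjusted p = 0.184). By fry, airway secretory genes passed (adjusted p = 0.0256), and interferon-response (0.144) and cell cycle genes (0.680) did not. NDRG1 did not pass with the mean of its probe sets (1.01, adjusted p = 0.204). By limma 5668 genes passed, 3630 higher (64.0%) and 2038 lower, against a median of all genes of 0.12; with the mean of each gene's probe sets 50.4% were higher. The count was 0 without any 1 of the 4 A549 arrays (3D control, 3D gefitinib, 2D control or 2D gefitinib), where the spread came from HCC827 alone, 8643 without the HCC827 3D control array and 8830 without the HCC827 2D control array.

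The measured integrity of the RNA differed in the same contrast, the mean over both lines, in which these gene groups differed. The actin 3' minus 5' difference was 2.10 ± 0.47 (SD) in the 4 3D arrays and -0.10 ± 0.04 in the 4 2D arrays, a difference of 2.19 (two-sided exact permutation p = 0.0286, the smallest that 70 splits allow). The GAPDH 3' minus 5' difference was 0.91 ± 0.48 against -0.02 ± 0.02, a difference of 0.93 (exact permutation p = 0.0286). Per array, actin stood at 1.67 and 1.74 in the A549 3D control and gefitinib arrays and at 2.34 and 2.64 in those of HCC827. Background probe sets lay at 6.69 in 3D and 6.71 in 2D (exact permutation p = 0.486).

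Within HCC827 (4 arrays), the question was which genes the scaffold changed in the EGFR-mutant line. PIGR was higher in 3D by log2 3.69 ± 0.11 (adjusted p = 0.0106), the proline dehydrogenase PRODH by 3.59 ± 0.22 (0.0106), the transcription factor NFATC4 by 3.12 ± 0.11 (0.0106) and the leukotriene receptor LTB4R by 2.87 ± 0.18 (0.0106). NFATC4 stood at -0.047 without the HCC827 3D control array, where another of its probe sets had the highest mean. PKIB, a kinase inhibitor (-3.08 ± 0.32, adjusted p = 0.0112), CNN3 (-2.86 ± 0.15, 0.0106), IFIT1 (-2.74 ± 0.29, 0.0112), SRP9 (-2.68 ± 0.14, 0.0106) and VIM (-2.41 ± 0.40, 0.0194) were lower. All of these moved the same way in 2 of 2 pairs, which the naming rule required of the largest changes. Interferon-response genes had a median of -1.18, 1 higher and 17 lower of 25 (2 and 19 adjusted over the list alone). Members included OAS1 at -2.21 ± 0.36 and IFI6 at -2.05 ± 0.22. Camera gave the list adjusted p = 2.82e-06, and adjusted p = 0.905 with an estimated correlation. EPSTI1, also lower (-2.26 ± 0.36), is not a member of that list. Airway secretory genes had a median of 1.34, 10 higher and 0 lower of 19 (10 and 0 adjusted over the list alone), including MUC4 (2.73 ± 0.12). Their camera result was adjusted p = 5.47e-04, and adjusted p = 0.905 with an estimated correlation. Fry gave adjusted p = 0.0268 for airway secretory and 0.128 for interferon-response genes. Hypoxia genes had a median of 0.34, with 1 higher and 0 lower of 24 (0 and 0 adjusted over the list alone, camera adjusted p = 0.701). This median averages unlike pairs, as labelled. The 3D minus 2D difference of the gefitinib pair minus that of the control pair had a median of -2.54 (23 of 24 below 0). The actin measure in these arrays was 2.34 and 2.64 in 3D, against -0.09 and -0.10 in 2D. By limma 3986 genes passed, 2349 higher (58.9%) and 1637 lower, and 44.4% were higher with the mean of each gene's probe sets. The count was 0 without any 1 of the 4 A549 arrays (3D control, 3D gefitinib, 2D control or 2D gefitinib), and 7522, 6748, 7686 and 6904 without the HCC827 3D control, 3D gefitinib, 2D control and 2D gefitinib arrays.

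The same question in A549 (4 arrays) gave ANGPTL4, higher in 3D by log2 4.10 ± 0.94 (adjusted p = 0.0468, and 0.0509 with a robust variance prior), the growth factor binding protein IGFBP5 by 3.91 ± 0.28 (0.0177), transferrin, TF, by 3.52 ± 0.30 (0.0177) and MALAT1 by 3.44 ± 0.12 (0.0177). The differentiation inhibitors ID4 (-3.66 ± 0.44, adjusted p = 0.0191) and ID2 (-2.47 ± 0.40, 0.0256) were lower, with the citric acid cycle enzyme SUCLA2 (-2.27 ± 0.18, 0.0177) and SRP9 (-2.26 ± 0.14, 0.0177). All moved the same way in 2 of 2 pairs, again by the naming rule. Hypoxia genes had a median of 1.53, 6 higher and 0 lower of 24 (7 and 0 adjusted over the list alone), with the aldolase ALDOC at 3.01 ± 0.49, the MYC antagonist MXI1 at 1.76 ± 0.18 and the histone demethylase KDM3A at 1.72 ± 0.16. The list had camera adjusted p = 0.0426, and adjusted p = 0.914 with an estimated correlation. Cell cycle genes had a median of -0.80, 36 of 39 below 0, with camera adjusted p = 3.65e-04, and adjusted p = 0.914 with an estimated correlation. No single member passed (0 higher and 0 lower, both over all genes and adjusted over the list alone): CCNB1 stood at -2.34 ± 0.76 (adjusted p = 0.0956) and MCM6 at -1.74 ± 0.59 (0.104). Neither list passed by fry (adjusted p = 0.319 for hypoxia, 0.777 for cell cycle). Interferon-response genes had a median of -0.01 (camera adjusted p = 0.359; 2 higher and 0 lower of 25, 0 and 0 adjusted over the list alone). Airway secretory genes had a median of 0.40 (camera adjusted p = 0.0802; 8 higher and 0 lower of 19, 8 and 0 adjusted over the list alone). The actin measure was 1.67 and 1.74 in 3D, against -0.05 and -0.14 in 2D. By limma 2665 genes passed, 1948 higher (73.1%) and 717 lower, and 54.8% were higher with the mean of each gene's probe sets and 53.3% with the largest-variance probe set. This count was 0 without any 1 of the 4 A549 arrays (3D control, 3D gefitinib, 2D control or 2D gefitinib), and 7559, 7548, 7661 and 7639 without the HCC827 3D control, 3D gefitinib, 2D control and 2D gefitinib arrays.

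Whether the lines differed in their response to the scaffold was tested as an interaction. Interferon-response genes had a median difference (HCC827 minus A549) of -1.04, 24 of 25 below 0, with 0 of 25 past the threshold over all genes and 0 higher and 15 lower adjusted over the list alone. By camera, adjusted p = 2.93e-08 for the list, and adjusted p = 0.689 with an estimated correlation. Hypoxia genes differed by a median of -1.13, 0 of 24 past the threshold both over all genes and adjusted over the list alone (camera adjusted p = 0.0119, and adjusted p = 0.872 with an estimated correlation). This value averages unlike HCC827 pairs. The hypoxia 3D minus 2D difference of the gefitinib pair minus that of the control pair had a median of -2.54 in HCC827, as labelled, and -0.19 in A549. A weaker hypoxia rise in untreated HCC827 is therefore not shown. The actin 3' minus 5' difference also shifted more with culture in HCC827 (2.59) than in A549 (1.80), beside both lists. EGFR stood at 0.45 ± 0.43 (adjusted p = 0.695) and DUSP6 at 0.90 ± 2.37 (0.901). Across genes the culture effects of both lines correlated with r = 0.739 (Spearman's rho 0.752; genes are not independent replicates). Of 1886 genes past the threshold in both lines, 1318 were higher in 3D in both (384 if the calls were independent), 555 lower in both (98.4) and 13 opposite. Limma called 0 genes for the interaction itself, with 1696 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0974, and fry 1 list, the lung alveolar genes. Without the HCC827 3D control, 3D gefitinib, 2D control and 2D gefitinib arrays it called 4361, 3448, 4515 and 3609.

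The gefitinib comparison asked how each line responded in each culture; with 1 array per condition these differences carry no replicate error of their own. In HCC827 3D, the gefitinib array minus the control array was log2 -3.32 for DUSP6, -1.79 for the ERK-driven transcription factor ETV5, -1.78 for CCND1, -1.53 for the proliferation marker MKI67 and -0.74 for the feedback inhibitor SPRY4. A limma fit without the HCC827 2D arrays, chosen after the data were seen, takes its spread from A549 alone and assumes that HCC827 varies alike; it gave DUSP6 -3.32 ± 0.15 (adjusted p = 3.03e-06), ETV5 -1.79 ± 0.17 (8.31e-05) and CCND1 -1.78 ± 0.15 (5.34e-05). In HCC827 2D, the array labelled gefitinib stood above the array labelled control in the same genes: DUSP6 by 3.64, ETV5 by 2.52, CCND1 by 2.51, MKI67 by 1.95 and SPRY4 by 0.61. DUSP6 signals were 11.48 and 8.16 in the 3D control and gefitinib arrays, and 6.57 and 10.21 in the 2D arrays labelled control and gefitinib. The deoxynucleotide enzyme RRM2 (2.41 in 2D, -3.21 in 3D) and the stress regulator DDIT4 (2.17, -2.90) followed the same pattern, and FILIP1L, which encodes a relative of filamin-interacting protein, the reverse (-3.46, 1.78). Of 214 genes at least 2-fold apart in both HCC827 pairs, 206 went opposite ways and 8 the same way; across all tested genes r was -0.555 (Spearman's rho -0.436), over genes that are not independent replicates. In A549, DUSP6 differed by -0.46 in 2D and -0.06 in 3D, and the largest differences included CCDC80 (1.08) and TFF1 (-1.28) in 2D and NEO1 (1.36) and TOP2A (-0.85) in 3D. Genes at least 2-fold higher and lower with gefitinib numbered 281 and 193 in HCC827 2D, 95 and 376 in HCC827 3D, 1 and 2 in A549 2D, and 1 and 0 in A549 3D. The A549 responses in 2D and 3D correlated with r = 0.237 (rho 0.240).

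**Figure D1:**
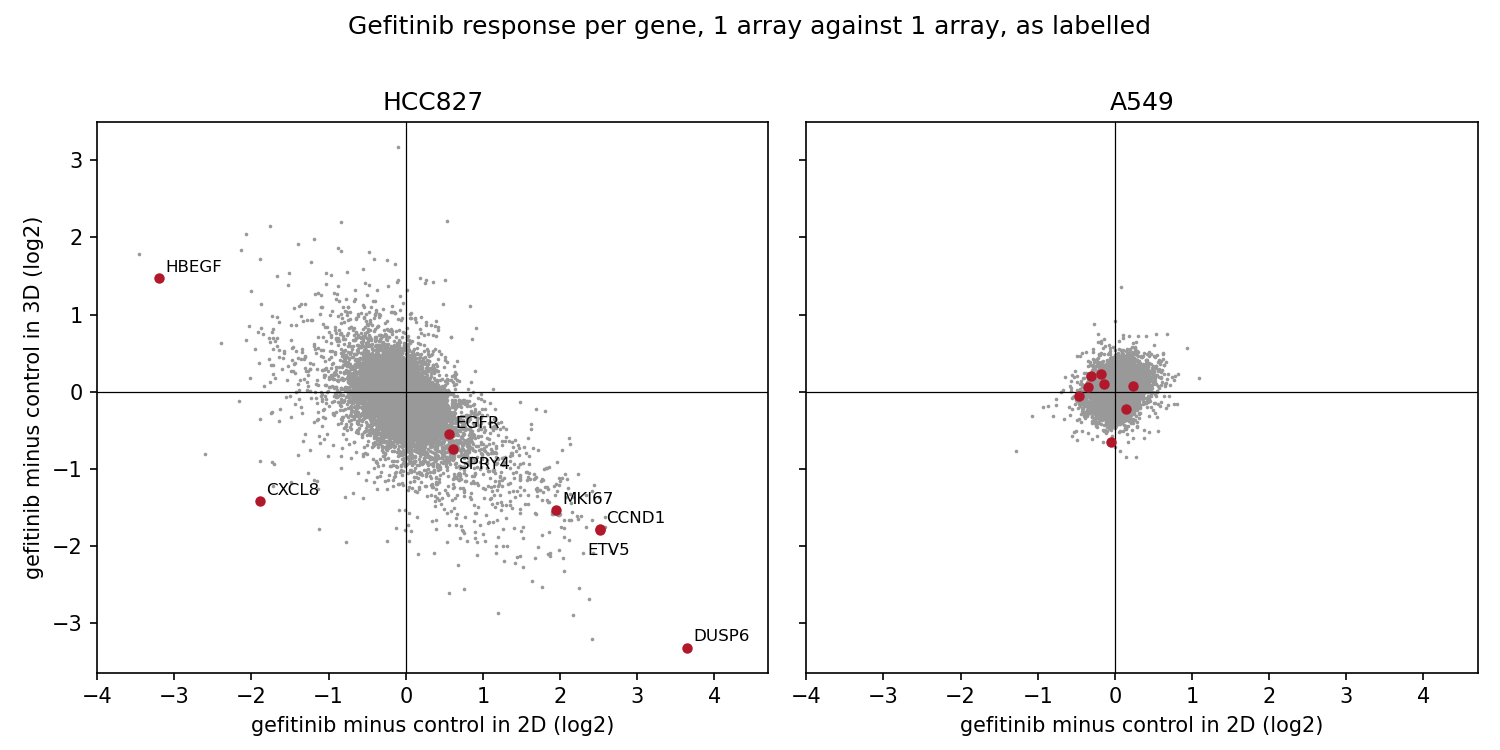
Log2 difference between the array labelled gefitinib and the array labelled control for each tested gene, in 2D (horizontal) and 3D (vertical), with 1 panel for HCC827 and 1 for A549 and named genes in red. DUSP6 lies at 3.64 and -3.32 in HCC827 and at -0.46 and -0.06 in A549.

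Among the gene lists, MAPK output, cell cycle and hypoxia genes followed the same division, while NF-kB and cytokine genes did not. MAPK output genes, transcribed downstream of ERK, had a median of 0.95 in the HCC827 2D pair as labelled (18 of 20 higher) and -1.26 in the 3D pair (18 of 20 lower), against -0.19 and -0.02 in A549 2D and 3D. Cell cycle genes had 1.85 (39 of 39 higher) and -1.34 (39 of 39 lower) in HCC827, and 0.06 and -0.27 in A549. Hypoxia genes had 0.72 and -1.68 (23 of 24 lower) in HCC827, and -0.03 and -0.18 in A549; in HCC827 the oxygen-response genes NDRG1 (1.64, -2.45) and EGLN3 (0.75, -2.56) took part. NF-kB and cytokine genes had medians below 0 in both HCC827 pairs, -0.93 in 2D as labelled (15 of 19 lower) and -0.62 in 3D (16 of 19 lower), and stood at -0.06 and -0.07 in A549. The chemokines CXCL8 (-1.89, -1.42) and CXCL5 (-2.60, -0.80) were lower in both. The HCC827 medians of MAPK output, cell cycle, hypoxia and NF-kB genes lay beyond all 10000 random lists in each culture. So did those of MAPK output in A549 2D (17 of 20 lower) and of cell cycle (35 of 39 lower) and hypoxia genes (21 of 24 lower) in A549 3D. Members of random lists are drawn independently, so a list whose genes move together leaves their range easily. These positions are therefore no test of gefitinib. In the HCC827 3D pair the RNA measures differed too: actin 3' minus 5' was 2.34 in the control and 2.64 in the gefitinib array, and GAPDH 0.97 and 1.57.

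**Figure D2:**
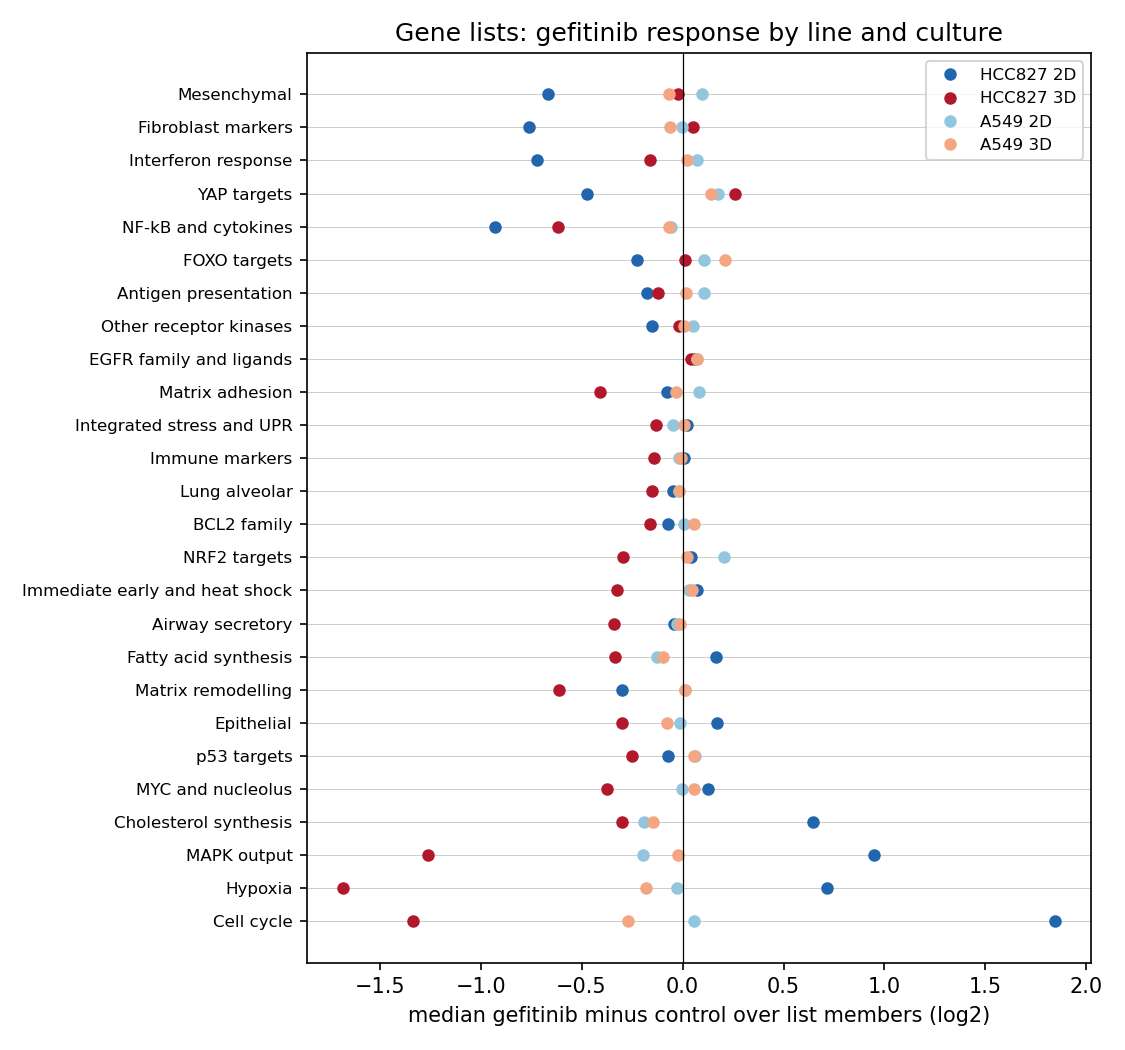
Median log2 difference between gefitinib and control arrays, as labelled, for each of 26 gene lists in HCC827 2D, HCC827 3D, A549 2D and A549 3D. Cell cycle genes stand at 1.85 in HCC827 2D, -1.34 in HCC827 3D, 0.06 in A549 2D and -0.27 in A549 3D.

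As a mean of 2D and 3D in HCC827 (2 pairs of arrays), which takes the 2D arrays as labelled, the gefitinib effect was tested. CXCL8 stood at -1.66 ± 0.19 (adjusted p = 0.926), CXCL5 at -1.70 ± 0.45 (0.926), IFI44L at -1.32 ± 0.21 (0.926) and VIM at -1.12 ± 0.40 (0.926), each below 0 in 2 of 2 pairs but none past the threshold. DUSP6 (0.16 ± 1.67, 0.994), ETV5 (0.36 ± 1.05, 0.979) and CCND1 (0.37 ± 1.04, 0.977) averaged opposite pairs: DUSP6 was -3.32 without the HCC827 2D control array and 3.64 without the HCC827 3D control array. NF-kB and cytokine genes had a median of -0.65, 17 of 19 below 0, with 0 members past the threshold over all genes and 8 lower adjusted over the list alone. Their camera adjusted p was 1.86e-09, and adjusted p = 0.881 with an estimated correlation. Interferon-response genes had -0.42, 25 of 25 below 0, with 0 over all genes and 2 lower adjusted over the list alone (camera adjusted p = 1.53e-09, and adjusted p = 0.960 with an estimated correlation). The interferon fall lay in the 2D pair as labelled (median -0.72, 25 of 25 lower); the 3D pair stood at -0.16 (17 of 25 lower, percentile 18.6 of random lists), and without the HCC827 2D arrays the list did not pass (mean -0.23, adjusted p = 0.525). Matrix remodelling genes, among them the urokinase receptor PLAUR (-0.81 ± 0.25) and the protease MMP7 (-0.76 ± 0.59), had -0.39, with 0 over all genes and 0 adjusted over the list alone (camera adjusted p = 8.20e-04, and adjusted p = 0.881 with an estimated correlation). In the 3D pair PLAUR stood at -1.26 and MMP7 at 0.37, so the mean fall of MMP7 lay in the 2D pair as labelled. Cell cycle genes had 0.21 and cholesterol synthesis genes 0.10, with 0 in each over all genes and 0 adjusted over the list alone (camera adjusted p = 8.20e-04 and 0.00343, and adjusted p = 0.960 for each with an estimated correlation). Cell cycle genes did not pass with cyclic loess (adjusted p = 0.248) or without the filter (0.0570), and both lists had means below 0 without the HCC827 2D arrays (-1.43 and -0.36). MAPK output genes had a median of 0.04 and a mean of -0.05, and camera's direction was up (adjusted p = 0.437), so mean and test differ in sign. Fry called 0 lists and limma 0 genes, with 487 at an unadjusted p under 0.05 and a smallest adjusted p of 0.926. Limma called 0 genes without any 1 A549 array and 2596, 2569, 3223 and 3214 without the HCC827 3D control, 3D gefitinib, 2D control and 2D gefitinib arrays, where the spread came from A549 alone.

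In A549 (2 pairs of arrays) the same test gave DUSP6 at -0.26 ± 1.67 (adjusted p = 1.00), MKI67 at -0.35 ± 0.85 (1.00), CDH1 at 0.31 ± 0.12 (1.00) and EGFR at -0.04 ± 0.30 (1.00). Cholesterol synthesis genes, with the sterol sensor INSIG1 at -0.56 ± 0.49 and the reductase DHCR7 at -0.40 ± 0.36, had a median of -0.15, 13 of 15 below 0, and 0 members past the threshold over all genes or adjusted over the list alone. The camera test gave adjusted p = 0.00110, and adjusted p = 0.979 with an estimated correlation. MAPK output genes had a median of -0.07 (camera adjusted p = 0.128). The error of DUSP6 above, ± 1.67, came mostly from the HCC827 pairs, since its A549 differences were -0.46 in 2D and -0.06 in 3D. Limma called 0 genes, with 86 at an unadjusted p under 0.05 and a smallest adjusted p of 1.00, and fry 0 lists. Without the HCC827 2D control array limma called 2. The number at an unadjusted p under 0.05 was 4 without the A549 3D control or 3D gefitinib array, 14 without the A549 2D control or 2D gefitinib array, and 1434, 1429, 1458 and 1449 without the HCC827 3D control, 3D gefitinib, 2D control and 2D gefitinib arrays; it was 1394 with A549 alone (smallest adjusted p 0.0696).

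Whether the lines differed in the gefitinib response, averaged over cultures with the HCC827 2D arrays as labelled, was the final contrast. DUSP6 differed by 0.42 ± 2.37 (HCC827 minus A549, adjusted p = 0.997) and EGFR by 0.04 ± 0.43 (0.997). NF-kB and cytokine genes differed by a median of -0.68, with 0 members past the threshold over all genes and 4 lower adjusted over the list alone (camera adjusted p = 1.22e-06, and adjusted p = 0.844 with an estimated correlation). Interferon-response genes differed by -0.57, with 0 members past the threshold over all genes or adjusted over the list alone (camera adjusted p = 6.37e-07, and adjusted p = 0.844 with an estimated correlation), and MAPK output genes by 0.10 (0.0849). Without the HCC827 2D arrays the interferon list did not pass (mean -0.27, adjusted p = 0.585), MAPK output turned to a mean of -1.06 and DUSP6 to -3.06 (4.32e-05). Limma called 0 genes, with 348 at an unadjusted p under 0.05 and a smallest adjusted p of 0.997, and fry 0 lists. The limma count was 0 without any 1 A549 array and 2302, 2274, 2452 and 2424 without the HCC827 3D control, 3D gefitinib, 2D control and 2D gefitinib arrays.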

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

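Of the tests in this part, those of exchanged HCC827 2D labels, of low RNA quality of the HCC827 3D gefitinib array, of an opposite response in 3D, of RNA integrity, of culture as such and of interferon genes with exchanged pairs, and the restriction of 1 count to 34 splits, were chosen only after the result was seen.

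The gefitinib response of HCC827 differed between 3D and 2D, a difference that was not tested since each condition had 1 array: the 3D pair lay on the other side of 0 from the 2D pair, as labelled, in the medians of MAPK output (3D minus 2D -2.08), cell cycle (-3.22), hypoxia (-2.54) and YAP target genes (0.61). An HCC827 2D array exchanged with a 3D array was tested on 327 of the 500 largest culture genes of A549. They were those at least 2-fold apart between 3D and 2D in HCC827 as labelled, and 95.7% (SE 1.12) placed both HCC827 2D arrays on the 2D side. An exchange would change which genes are taken, so this share cannot decide. Read after the result was seen, the array correlations argue against that exchange. Across probe sets r was 0.977 in the HCC827 2D pair, 0.978 in the 3D pair and 0.889 to 0.923 between them. The tables argue against a 2D array exchanged with an A549 array, since 98.8% of 500 line genes placed both HCC827 2D arrays on the HCC827 side. Low RNA quality of the HCC827 3D gefitinib array may contribute to the 3D falls: its actin 3' minus 5' difference exceeded that of its control by 0.30, against sizes of at most 0.09 in the other pairs, while the 2D pair does not hold that array. Exchanged labels of the HCC827 2D arrays stay open: the responses correlated with r = -0.536 over 11476 genes in no list, which restates the r of -0.555 over all tested genes and would follow from an opposite response too. A response to gefitinib whose direction differs between 2D and 3D stays open as well. With 1 array per condition it cannot be told apart from exchanged labels. Gefitinib inhibits EGFR, so a fall of genes downstream of ERK is the direction to look for. The 3D pair showed it (MAPK output median -1.26) and the 2D pair as labelled showed the reverse (0.95), so the 2D pair is the unusual one.

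Control probe sets outside the gene comparisons differed between 3D and 2D: the actin 3' minus 5' difference by 2.19, that of GAPDH by 0.93, poly-A spike-in controls by 2.97, hybridisation controls by 1.26 and the Alu control by 1.28 (exact permutation p = 0.0286 for each). With the cell line as a term, the split by culture gave 5966 genes. Of the 34 splits that can be fitted so, 1, the real one, gave as many, and the highest other gave 1. Fitted without that term, the culture split gave 2586 genes and the cell-line split, which follows the other design factor, 3370, so 2 of 35 gave as many. Every other split mixes 3D and 2D arrays, which puts the culture difference into its residual, so few genes could pass in it. With 1 array per condition, these counts cannot exclude chance differences between single cultures. RNA integrity or amplification may account for part of the genes differing between 3D and 2D. Probe sets of 1 gene agreed less on the culture difference than on the line difference (intraclass correlation, culture minus line, -0.309, 95% interval -0.330 to -0.287, 7062 genes). Culture as such cannot be told apart from RNA preparation, because 0 of the 3D arrays had an actin difference inside the 2D range. Nor can it be told apart from whatever set the hybridisation controls higher in 3D (11.6 to 12.4) than in 2D (10.6 to 10.8). The cause of that difference was not tested. For the genes differing between the lines, the real split gave 3370 genes, 1 of 35 splits gave as many, and the highest other, the split by culture, gave 2586. Other splits mix the lines in the same way, so chance is not excluded here either.

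Interferon-response genes differed between the lines in their culture effect by a median of -1.04 (camera adjusted p = 2.93e-08, and adjusted p = 0.689 with an estimated correlation), being lower in 3D in HCC827. In A549 the median over 17 members above the array median in both 2D arrays was -0.00757, against -0.83 in proportion to its actin shift (bootstrap SE 0.161). This argues against a fall in proportion to that shift. It does not settle RNA integrity as a cause, since the list stood lower in A549 than in HCC827 and so had less room to fall. The mean was not set by 1 of the pairs of HCC827 arrays: the smaller fall was -0.98 (20 of 25 lower, SD of random lists 0.163) and the other -1.08, and with the 2D labels exchanged they would be -0.58 (SD 0.138) and -1.67. A different change of interferon-stimulated transcription in the EGFR-mutant line on the scaffold may remain as a hypothesis. RNA integrity, time in culture and cell number stand next to it. All differed with culture, and time in culture and cell number were not tested.

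In the same interaction of line and culture, camera also passed the hypoxia genes (median -1.13), immediate early and heat shock genes (-0.51), epithelial genes (0.30), mesenchymal genes (-0.84), lung alveolar genes (0.22) and airway secretory genes (0.46). With an estimated correlation, adjusted p was 0.872 for hypoxia and 0.689 for the others. The actin 3' minus 5' shift with culture, 2.59 in HCC827 and 1.80 in A549, differed beside these lists. The hypoxia value also averages HCC827 pairs whose culture differences lay apart by a median of -2.54, gefitinib pair minus control pair as labelled. Limma called 0 members of each over all genes; adjusted over the list alone it called 2 higher and 0 lower epithelial, 1 and 3 mesenchymal, 6 and 3 airway secretory and 0 of the hypoxia, immediate early and heat shock and lung alveolar genes. In the interaction of line and gefitinib, which takes the HCC827 2D arrays as labelled, camera passed cell cycle (0.32), cholesterol synthesis (0.21), matrix remodelling (-0.36), interferon-response (-0.57) and NF-kB genes (-0.68), and adjusted p was 0.844 for each with an estimated correlation. Over all genes 0 members of these lists passed, and adjusted over the list alone 4 NF-kB genes, lower, and 0 of the others. Without the HCC827 2D arrays, interferon-response genes lost this call (mean of the members -0.27, adjusted p = 0.585) and cell cycle (-1.31) and cholesterol synthesis genes (-0.17) reversed. Matrix remodelling lost it with the mean of probe sets (0.642) and without the HCC827 3D arrays (0.203), and cell cycle with cyclic loess (0.0625) and without the filter (0.118).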

How the results depend on the processing

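Leaving out both HCC827 2D or both HCC827 3D arrays was chosen only after the data were seen; the other alternatives were fixed before. Of 170 values of single genes, 170 kept their direction and their side of the threshold without the filter and without the variance trend, 169 with median centring, robust moderation and all pairwise interactions, and 167 with cyclic loess. The fit of HCC827 alone held fewer of these values: 25 no longer passed and 25 kept direction and side of the threshold. In that fit 0 genes passed for culture. Leaving out 1 A549 array ended 79 (2D control, 2D gefitinib) or 80 (3D control, 3D gefitinib) calls. Leaving out the HCC827 2D control, 2D gefitinib, 3D control or 3D gefitinib array reversed 18, 11, 9 and 7 values. IFI6 in the mean culture effect had an adjusted p of 0.0673 in an additive fit. List tests were not repeated with single arrays left out. Where no other reason is given, the cause was not tested.

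Gene counts moved by more than 1.5 times as follows. Culture in A549 gave 4669 genes (2490 higher, 2179 lower) with the probe set of largest variance, 1709 with all pairwise interactions, 7407 with A549 alone, 7618 without both HCC827 2D arrays and 7509 without both HCC827 3D arrays. In HCC827 the culture count was 0 with that line alone (3551 at an unadjusted p under 0.05). Gefitinib in HCC827 gave 3116 (773 higher, 2343 lower) without its 2D arrays and 2490 (1109 and 1381) without its 3D arrays, and the gefitinib difference between lines 2368 and 2194. In those fits, by construction, the spread comes from A549 alone. With a 2-fold minimum, the line, mean culture, HCC827 culture and A549 culture counts were 1889, 1049, 1462 and 909. The share of genes higher in 3D, 64.0% in the mean of both lines, was 50.4% (2787 higher, 2739 lower) with the mean of probe sets and 52.6% (3827, 3455) with the largest-variance probe set. In HCC827 these alternatives gave 44.4% (1849, 2316) and 47.3% (2783, 3103), and in A549 the mean of probe sets gave 54.8% (1503, 1239). The median of all genes in the mean culture effect was 0.12, 0.16 with cyclic loess and 0.13 with median centring.

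Leaving out each array in turn gave 1730 to 8550 genes for the line, 0 to 8830 for the mean culture effect, 0 to 7686 for culture in HCC827 and 0 to 7661 in A549. It gave 0 to 4515 for the culture difference, 0 to 3223 for gefitinib in HCC827, 0 to 2 in A549 and 0 to 2452 for the gefitinib difference. Without any 1 A549 array the spread comes from HCC827 alone, and all 3 culture counts were 0. For the line, CCND1 ranged from -1.89 to 0.25, DUSP6 from -2.14 to 1.34 and MKI67 from -1.27 to 0.47. For the mean culture effect, CCND1 ranged from -1.41 to 0.73, DUSP6 from -0.76 to 2.72, ETV5 from -0.70 to 1.45 and MKI67 from -0.96 to 0.78. For culture in HCC827 the ranges were -2.85 to 1.44 (CCND1), -2.05 to 4.91 (DUSP6), -2.11 to 2.20 (ETV5), -1.65 to 1.84 (MKI67), -0.047 to 3.24 (NFATC4) and -0.42 to 0.93 (SPRY4). DUSP6 ranged from -2.58 to 4.38 in the culture difference and from -3.06 to 3.90 in the gefitinib difference. For gefitinib in HCC827 the ranges were -1.78 to 2.51 (CCND1), -1.28 to 2.41 (CDC20), -3.32 to 3.64 (DUSP6), -0.55 to 0.56 (EGFR), -1.79 to 2.52 (ETV5), -1.06 to 2.07 (KIF20A), -1.53 to 1.95 (MKI67) and -0.74 to 0.61 (SPRY4).

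Directions reversed with the mean of probe sets for ALG13 (-0.029) and CDH1 (-0.40, adjusted p = 0.0172) in the mean culture effect. With the largest-variance probe set they reversed for SPRY4 in the line (0.33, 0.0420) and CDH1 in the mean culture effect (-0.86, 0.00250) and in HCC827 (-0.98, 0.00623), each past the threshold in the new direction. For gefitinib in HCC827 without its 2D arrays, they reversed for DUSP6 (-3.32), ETV5 (-1.79), CCND1 (-1.78), MKI67 (-1.53), CDC20 (-1.28) and KIF20A (-1.06), and so did the mean log2 of the members for cell cycle (-1.43), cholesterol synthesis (-0.36) and MAPK output (-1.15). In the gefitinib difference these were -3.06 for DUSP6, -1.31 for cell cycle, -0.17 for cholesterol synthesis and -1.06 for MAPK output. Without the 3D arrays SPRY4 was 0.61. The reversals in this contrast follow from leaving 1 of 2 opposite pairs.

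Lists past the threshold numbered 3 for the line, 3 for the mean culture effect, 2 for culture in HCC827, 2 in A549, 7 for the culture difference, 5 for gefitinib in HCC827, 1 in A549 and 5 for the gefitinib difference. With an estimated correlation there were 0 in each of the 8. Without the filter there were 6 for the line, 6 for culture in HCC827, 3 for gefitinib in A549 and 8 for the gefitinib difference. The mean of probe sets gave 4 for culture in HCC827 and 2 for gefitinib in A549, and cyclic loess 2 for the latter. Fry gave 12 for the line, 4 for the mean culture effect (1 shared with camera), 3 for culture in HCC827 (1 shared), 2 in A549 (0 shared), 1 for the culture difference and 0 for gefitinib in HCC827, in A549 and for their difference. Without the HCC827 2D arrays there were 10, 8 and 9 for gefitinib in HCC827, in A549 and their difference, and without the 3D arrays 12, 8 and 11, with 4 for culture in A549.

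The correlation of the HCC827 responses in 2D and 3D was -0.493 without the filter and -0.568 with cyclic loess, and that of A549 0.257, 0.204 and, with the mean of probe sets, 0.254. The 3D minus 2D medians in HCC827 were -3.11 (cell cycle) and -2.26 (hypoxia) with cyclic loess, and with the mean of probe sets -1.78 (MAPK output), -2.72 (cell cycle) and -2.10 (hypoxia), with MAPK output in A549 at 0.11. With 1 array per condition, no response within a line and culture has an error of its own, and 6318 genes whose signal exceeded the array median in fewer than 2 arrays were not tested.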

Other observations

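In the mean of both lines, 4 of 11 EGFR family genes and 9 of 24 hypoxia genes differed between 3D and 2D, against 5668 of 11926 genes in all; EGFR itself did not pass (adjusted p = 0.130), nor did the hypoxia list by camera (0.184). ERBB2 was higher in 3D by log2 1.25 ± 0.10 (adjusted p = 0.00434), ERBB3 by 0.71 ± 0.09 (0.00742) and the receptor inhibitor LRIG1 by 0.55 ± 0.12 (0.0241), and the ligand NRG1 was lower, at -1.13 ± 0.12 (0.00523). Of 11 members, 3 were higher and 1 lower (3 and 1 adjusted over the list alone), with a list median of -0.07, a mean of 0.06 and, unlike the mean, a downward direction in camera (adjusted p = 0.879). The angiogenic factor VEGFA was higher by 2.29 ± 0.40 (0.0137) and the glycolytic regulator PFKFB4 by 2.21 ± 0.62 (0.0451); with the mean of a gene's probe sets they stood at 1.20 and 0.70 and no longer passed. None of these genes passed without any 1 of the 4 A549 arrays. These lists were picked for description after their values were seen.

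Of the 8 genes at least 2-fold apart in the same direction in both HCC827 pairs, the adhesion molecule ICAM1 differed by -1.15 in 2D as labelled and -1.16 in 3D, and the chemokine CXCL2 by -1.26 and -1.05. In A549 ICAM1 stood at 0.11 and -0.09 and CXCL2 at -0.10 and -0.04. Both were chosen after their values were seen, and these differences were not tested.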
